A study of Rattus norvegicus with 8 samples.

How the data were processed

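The series holds 8 rat exon arrays, each hybridised with RNA from the whole spinal cord of 1 female Lewis rat: 4 with EAE and 4 untreated controls. EAE was induced with 50 µg of guinea pig myelin basic protein in incomplete Freund's adjuvant with 4.0 mg/ml of Mycobacterium butyricum, injected at the tail base. Cords were flushed out of the spine and frozen, RNA was extracted with a QIAGEN RNeasy Lipid Tissue kit with DNase I, and it was amplified and biotinylated with NuGEN kits. No litter or batch is given per animal, so neither could be a term in a model.

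The values are log2 probe set intensities as deposited. Affymetrix Expression Console, RMA and Partek are named in the submitters' processing notes without their roles, order or versions, and the genome build is not given in the sources used here. A 2-way ANOVA in Partek is named for the study's own exon analysis, and its results were not used here. The table holds 80939 probe sets without missing values. Array means were nearly equal while SDs ran from 2.11 to 2.26, and correlations between arrays from 0.890 to 0.984. An array has no read depth, so the number of arrays limits the precision.

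Probe sets were joined to gene symbols with the platform's own annotation: 76186 had 1 symbol, 550 had several and 4203 had none. Of 7830 symbols 5983 stood in a current rat gene table and 1822 were updated through a synonym. Symbols are printed as the annotation gives them. No coordinates were used. A probe set was counted as measured at or above the 25th percentile of all values (log2 3.98) on at least 4 arrays, which left 62176, of which 58784 had 1 symbol. A gene's value on an array was the mean of its measured probe sets. Background was read from 1048 olfactory receptor genes with 2014 probe sets, whose 95th percentile was 4.77 in controls and 4.70 in EAE. The filter on dim probe sets was not applied to them, while tested genes hold only probe sets that passed it. These limits may thus be low for tested genes, and counts of genes at background too small.

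Genes (6961) and probe sets were compared, EAE minus control, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. All tests were 2-sided. Exon usage was tested with limma's diffSplice F test in 5563 genes with at least 3 measured probe sets. Gene lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01. Of 34 lists the B cell markers had too few measured genes, which left 33. Differences between lists were tested per array with exact permutation tests, whose smallest p for 4 against 4 arrays is 0.0286. Errors of changes are SE from limma, and those of group means are SD. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

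The comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Differences between lists were not among these comparisons. The rule took the 10 largest rises and 10 largest falls among genes past the threshold without overlap between groups and with at least 3 probe sets, and up to 3 members of each list with the largest change past the threshold. Where no member passed, it took the 2 largest changes, and it added the largest change against the list's direction. For exon usage it took the 10 smallest adjusted p among genes with a gene-level change under 1 and a probe set differing by 1 or more, and each passing gene with known alternative exons. The gene with the smallest adjusted p of these 10 is left out. For single probe sets it took the 2 largest rises and the 2 largest falls.

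The steps were tested on simulated data with the same size. The gene test recovered 27% of changes of 0.5 and 86% of changes of 1, with 7.38% of calls in unchanged genes. The probe set test recovered 92.8% of probe sets moved by 1 or 2, most of them by 2, with 5.18% false calls. diffSplice recovered 15% of genes with a probe set moved by 1 and 92% moved by 2, called 0.5% of genes shifted as a whole, and 25.7% of its calls held no moved probe set. A test with a variance of its own for each probe set, added after seeing the data, recovered 18% and 82% with 1.96% false calls. In genes shifted as a whole each probe set rose by 2, whether dim or bright. The 0.5% called there by diffSplice therefore cannot speak for dim probe sets that follow their gene less. The list test found the moved list and 0 others that share no gene with it. Noise was drawn independently for each gene, so this cannot check the preset correlation of 0.01. In the data the estimated correlation reached 0.512 (NK cell list).

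Alternatives covered the filter on dim probe sets, quantile normalization and median centring, the variance model, the gene summary, the exon usage test, the set test, a minimum change of 1 and leaving out each array. Chosen after seeing the data were a run without control 195 and EAE 218, the arrays of narrowest spread, a filter at the olfactory receptor background, centring on the tested genes, and a variance of its own for each probe set.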

Results

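RNA was profiled on rat exon arrays from whole spinal cords of 8 female Lewis rats aged 16 weeks. Experimental autoimmune encephalomyelitis (EAE), an inflammatory disease of the central nervous system driven by T cells, had been induced in 4 rats with myelin basic protein in adjuvant with mycobacteria, and their cords were taken on day 13, at the height of disease. The other 4 rats were untreated littermates of the same age. Each rat gave 1 array with 80939 probe sets, each probe set reading an exon or part of one. Because the controls received no injection, effects of the adjuvant and of the myelin protein are contained together in every EAE value. The number of arrays, 4 per group, limits the precision of each comparison.

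The first principal component of the gene values, with 70.2% of the variance, parted the EAE arrays from the controls. On the second, with 13.8%, control rat 195 lay farthest from the rest. Its array had the narrowest spread of log2 values (SD 2.11, against 2.17 to 2.26 on the others) and the highest median over olfactory receptor probe sets (3.77, against 3.16 to 3.49). Olfactory receptor genes, which are expressed mainly in the nose, served as a measure of background in the cord.

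**Figure D1:**
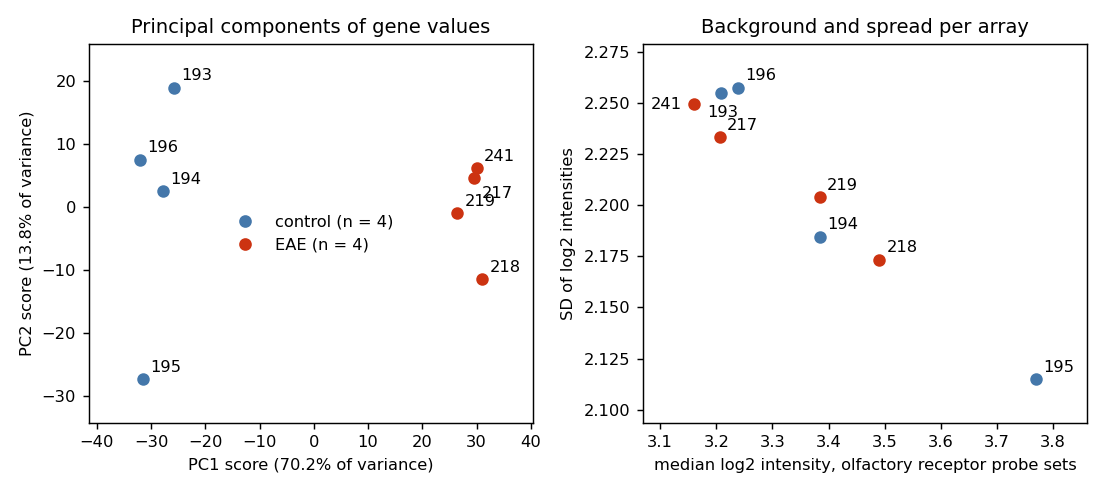
Left, scores of the 8 arrays on the first and second principal components of gene values, with the rat's number beside each point; right, the SD of log2 intensities of each array against its median log2 intensity over olfactory receptor probe sets. EAE (red) and control (blue) arrays separate along the first component, and control 195 has the highest background median, 3.77, and the lowest SD, 2.11.

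The comparison of rats with EAE against healthy controls asked which genes differ in expression in the diseased cord. The largest rises, among genes with at least 3 probe sets and no overlap between the groups, were in single MHC class II genes and chemokines. Cd74, the invariant chain of MHC class II, was 143-fold higher in EAE (log2 4.52 ± 0.12 in controls and 11.68 ± 0.13 in EAE, SD, n = 4 each), and H2-Ea, a class II chain now named RT1-Da, was 121-fold higher. The chemokines Cxcl9, Cxcl13 and Cxcl11 were 116-fold, 112-fold and 56.3-fold higher. The falls were smaller. Among genes with at least 3 probe sets and no overlap between the groups the largest were in the haemoglobin chain Hba-a2, which was 5.38-fold lower, in Idi1 of cholesterol synthesis (3.62-fold), in the desaturase Scd1 (3.17-fold) and in Cyp51, also of cholesterol synthesis (3.09-fold).

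Of 6961 genes tested with limma, 2164 changed at an adjusted p under 0.05: 951 rose and 1213 fell. By size the order was the opposite, since 445 genes rose by 1 or more on the log2 scale (2-fold or more) and 81 fell by as much. The median change over all genes was -0.11. The values of the 2 groups did not overlap in 2313 genes, or 33.2%, where chance gives 2.86%.

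The other genes among the 10 largest rises, all with 4 EAE rats above 4 controls, were Lcn2, an iron-siderophore binding protein (log2 change 6.28 ± 0.15, SE), the myeloid receptor Lilrb4 (64.0-fold higher), the interferon-induced GTPase Ifi47 (5.67 ± 0.18), the cytidine deaminase Apobec1 (5.54 ± 0.20) and Cybb, the catalytic subunit of the phagocyte NADPH oxidase (5.50 ± 0.15). In controls 9 of these 10 genes lay at or below the log2 value that 95% of olfactory receptor genes stayed under (4.77), Ifi47 (4.90) being the exception. Their folds are therefore measured against the background of the arrays. The same held for 178 of the 445 genes that rose by 1 or more. Among the 10 largest falls were also Scd1, a stearoyl-CoA desaturase (log2 change -1.66 ± 0.14 over 3 probe sets), Hnmt, which degrades histamine (-1.46 ± 0.13), Nrep (-1.43 ± 0.18, with EAE at background), the actin-binding Nexn (-1.42 ± 0.17), the glycosyltransferase Galnt13 (-1.41 ± 0.15), the amylase Amy1a (-1.41 ± 0.15) and Gabrg1, a GABA-A receptor subunit (-1.38 ± 0.22). All had adjusted p of 0.000961 or less in limma. Scd, a second entry whose symbol is also the current one of Scd1, was chosen after its values were seen: its value over 6 brighter probe sets differed by -0.39 ± 0.19 (adjusted p = 0.143) and did not pass.

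**Figure D2:**
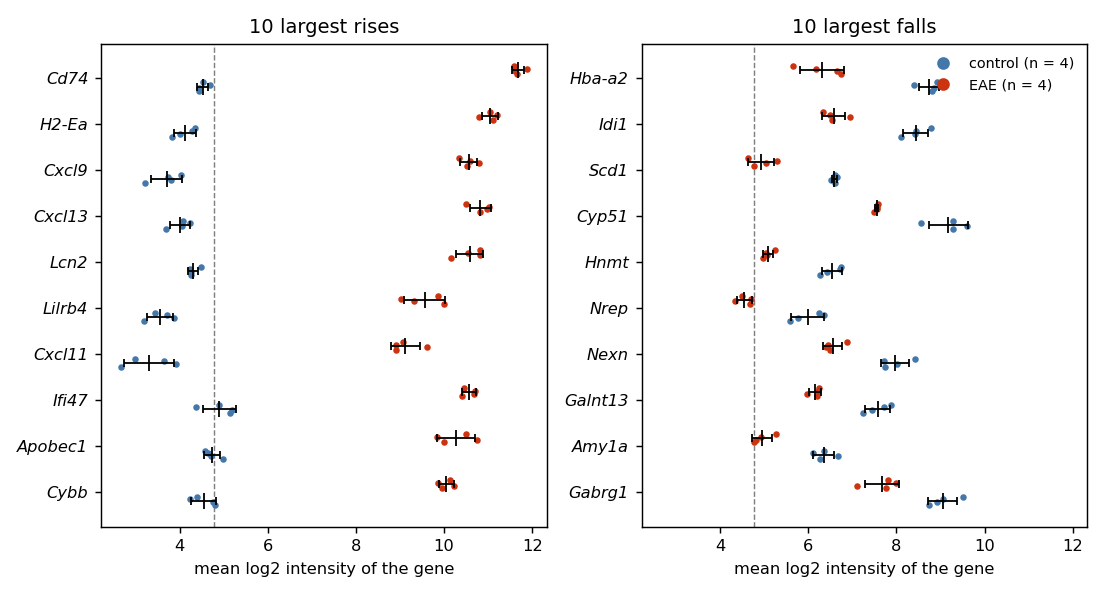
Mean log2 intensity of the 10 genes with the largest rise (left) and the largest fall (right); points are arrays, bars the mean ± SD of 4 rats per group, and the dashed line the 95th percentile of olfactory receptor genes in controls (4.77). Cd74 goes from 4.52 to 11.68, and Hba-a2 from 8.74 to 6.31.

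Genes were then grouped by lists of pathways and cell type markers, to see which groups moved together. Of 33 lists with enough measured genes, 15 rose and 5 fell in limma's camera test with a preset inter-gene correlation. With a correlation estimated from the data 12 lists still rose and none of the 5 falls passed, as given below for each list that lost its call. In camera with the estimated correlation the adjusted p of these 12 ran only from 0.0131 to 0.0410. The smaller values printed below for each list come from the preset correlation unless stated otherwise. Of the 35 ways to split the 8 arrays into 4 and 4, 12 gave at least 20 called lists, the real one included. The 11 others were among the 16 splits that swap 1 array of each group and so keep part of the difference between EAE and control, while the 18 that swap 2 gave at most 10. Each of the 20 list means lay wholly above or wholly below the controls in all 4 EAE rats. In controls RT1-Ba, RT1-CE5, Psmb9, Psmb8, Mx1, Il2rg, Il1rn, Il2ra, Cd8a, Cd2, Klrk1, Ccr2, C1qc, Coro1a, Cxcr3, Ly6c, Top2a, Serpina3n, Hmox1, Tlr2 and Egr2 lay at background, and their rises are measured against it.

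Antigen presentation rose as a whole. Of 9 measured genes of MHC class II presentation 8 rose (8 adjusted over the list alone; adjusted p = 5.04e-12), among them RT1-Ba (5.03 ± 0.11), and the list mean went from 5.19 ± 0.11 to 8.77 ± 0.15 (SD, n = 4). All 13 genes of class I presentation rose (13 adjusted over the list alone; adjusted p = 4.51e-12), with RT1-CE5 (4.86 ± 0.15) and the immunoproteasome subunits Psmb9 (3.38 ± 0.11) and Psmb8 (2.38 ± 0.17) in front. RT1 genes have close relatives in the rat genome, and the reading of one by probe sets of another was not excluded. Of 22 interferon response genes 18 rose (18 adjusted over the list alone; adjusted p = 1.36e-13), including Mx1, an antiviral GTPase (24.2-fold higher), and the guanylate-binding Gbp2 (4.12 ± 0.14).

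Chemokines and cytokines rose in part. Of 26 chemokines 13 rose and none fell (13 adjusted over the list alone; adjusted p = 2.02e-08). Of 36 cytokines and receptors 19 rose and 3 fell (20 and 5 adjusted over the list alone; adjusted p = 4.34e-08). Il2rg, the common receptor chain for interleukin-2 and its relatives (5.08 ± 0.11), the interleukin-1 antagonist Il1rn (3.25 ± 0.25) and Il2ra (2.90 ± 0.16) rose most. Il2 itself fell by 0.85 ± 0.22 on the log2 scale (adjusted p = 0.0146), but its change was -0.29 (adjusted p = 0.664) with dim probe sets removed at the 50th percentile, and without variance moderation its adjusted p was 0.0566. The other genes past the threshold with lower values were Il12a (-0.85 ± 0.13) and Csf3 (-0.44 ± 0.14), chosen after their values were seen. Csf3 lay at background in both groups, so its difference is between background readings.

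Markers of monocytes, macrophages and microglia rose. Of 24 monocyte and macrophage genes 23 rose (23 adjusted over the list alone; adjusted p = 2.81e-25), including the chemokine receptor Ccr2 (4.90 ± 0.26). All 8 measured markers of homeostatic microglia rose as well (8 adjusted over the list alone; adjusted p = 2.02e-08), by 1.12 (P2ry13) to 2.49 (the fractalkine receptor Cx3cr1), with Mertk (1.78 ± 0.18) and Aif1 (1.75 ± 0.12) between them. Of 13 T cell markers 9 rose (10 adjusted over the list alone; adjusted p = 2.90e-08), led by Cd4 (3.56 ± 0.15), Cd8a (2.29 ± 0.19) and Cd2 (2.03 ± 0.17). The adjusted p of the T cell list was 0.105 with an estimated correlation. Whole cords were read, and which cells held the RNA of these markers was not tested. Members of the microglia and T cell lists, Cd4 and Cx3cr1 included, could therefore have risen in cells of another type.

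Of 9 NK cell and cytotoxic genes 2 rose and 1 fell (4 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.105). Klrk1, an activating receptor, rose by 4.21 ± 0.16 and Gzmb, a granzyme, by 1.08 ± 0.23, although Gzmb changed by 0.15 (adjusted p = 0.545) once dim probe sets were removed at the 50th percentile. Perforin, Prf1, passed with a difference of -0.57 ± 0.16 (adjusted p = 0.0235), but it is read by 1 probe set that lay under the background of single probe sets (5.33) in both groups. Its change was 0.10 (adjusted p = 0.584) with no filter on dim probe sets, and its adjusted p rose to between 0.051 and 0.0653 without control 196, EAE 217, EAE 218 or EAE 219 and to 0.0611 without variance moderation. The list passed without EAE 241 (adjusted p = 0.0441), with no filter on dim probe sets (0.00959) and in limma's fry test (0.0138). None of 6 neutrophil genes and none of 7 mast cell genes passed (0 and 0 adjusted over the list alone), and the lists had adjusted p = 0.980 and 0.846. Their largest changes were -0.50 ± 0.20 for the chemokine receptor Il8rb (now Cxcr2), 0.34 ± 0.15 for S100a9, -0.32 ± 0.21 for the tryptase Tpsab1 and -0.31 ± 0.16 for Hdc, which makes histamine. Without control 193 Il8rb (adjusted p = 0.00195) and Tpsab1 (adjusted p = 0.0198) passed, with array quality weights Il8rb (0.00575) and Hdc (0.0340), and after centring on the tested genes Il8rb (0.0472). Il8rb and S100a9 lay at background in both groups. S100a9 differed by 0.20 without control 193, and without control 195 Tpsab1 differed by -0.16 and Hdc by -0.18.

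Genes of complement, innate sensing and proteolysis rose too. Of 13 complement genes 11 rose (11 rises and 1 fall adjusted over the list alone; adjusted p = 1.95e-10), with C3 (4.76 ± 0.17), the C1 inhibitor Serping1 (4.31 ± 0.21) and C1qc (3.47 ± 0.16) in front. Of 10 genes of pattern recognition and inflammasomes 9 rose (9 adjusted over the list alone; adjusted p = 8.33e-11), including the inflammatory caspases Casp4 (2.87 ± 0.10) and Casp1 (2.63 ± 0.11) and the receptor Tlr2 (2.53 ± 0.13). Of 25 proteases and inhibitors 13 rose (15 adjusted over the list alone; adjusted p = 2.02e-08), led by the lysosomal protease Ctsc (4.31 ± 0.21), the protease inhibitor Serpina3n (3.47 ± 0.47) and the metalloproteinase inhibitor Timp1 (8.01-fold higher). Of 14 genes of leukocyte adhesion and trafficking 9 rose (9 adjusted over the list alone; adjusted p = 4.05e-05), with Coro1a (1.65 ± 0.12), Cd44 (1.60 ± 0.13) and Cxcr3 (1.42 ± 0.19). Of 11 proliferation genes 3 rose and none fell (4 rises adjusted over the list alone), with Top2a (2.13 ± 0.38), Aurka (1.33 ± 0.16) and Aurkb (0.98 ± 0.13). The list passed with an adjusted p of 0.0045, but its adjusted p was 0.290 with an estimated correlation.

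**Figure D3:**
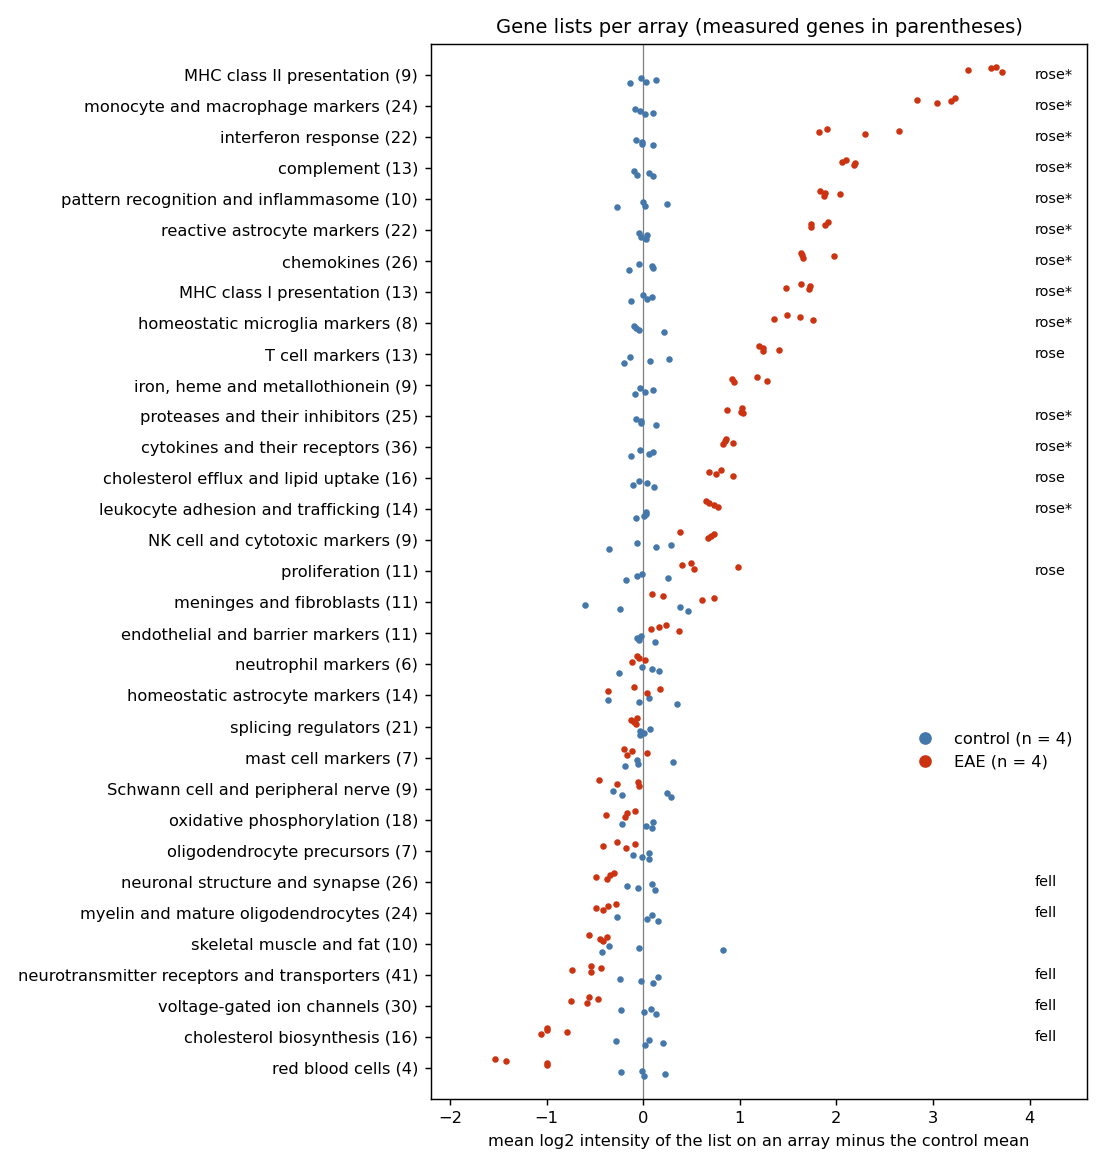
Mean log2 intensity of each of 33 gene lists on each array, minus the mean of the control arrays, with the number of measured genes in parentheses; points are rats. Lists marked as having risen or fallen passed the camera test with a preset correlation, and an asterisk marks those that passed with an estimated correlation too. MHC class II and monocyte lists lie highest, and cholesterol biosynthesis is the lowest of the called lists.

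Of 22 reactive astrocyte markers 17 rose and none fell (17 adjusted over the list alone; adjusted p = 1.22e-12), the largest being Lcn2, Serping1 and Gbp2. These 3 also stand in the iron, complement and interferon lists. Of the 22 markers 9 are shared with other lists, all 9 of which rose, and 8 of the 13 others rose. The homeostatic astrocyte list did not pass (adjusted p = 0.961). Of its 14 genes 3 rose, the glutamate transporter Slc1a3 (1.15 ± 0.19), the urea transporter Slc14a1 (0.80 ± 0.17) and the gap junction protein Gja1 (0.69 ± 0.17), and Fgfr3 fell by 0.37 ± 0.10 (3 and 4 adjusted over the list alone). The fall of Fgfr3 did not pass without control 196 (adjusted p = 0.055) or EAE 217 (adjusted p = 0.0607), and with the median of probe sets per gene neither Fgfr3 (0.269) nor Slc14a1 (0.0792) passed.

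Genes of myelin and of cholesterol synthesis fell. Of 24 myelin and mature oligodendrocyte genes 11 fell and none rose (14 adjusted over the list alone; adjusted p = 0.00202), with Ugt8, which makes the myelin lipid galactosylceramide (-1.18 ± 0.15), the connexin Gjb1 (-1.06 ± 0.11) and Opalin (-0.95 ± 0.21) lowest. This list had an adjusted p of 0.346 with an estimated correlation. Of 7 oligodendrocyte precursor genes 2 fell (2 adjusted over the list alone), Bcan (-0.66 ± 0.18) and the lineage factor Sox10 (-0.41 ± 0.10), and the list did not pass (adjusted p = 0.246). Bcan did not pass without control 196, EAE 218 or EAE 241 (adjusted p = 0.0508, 0.0536 and 0.0535) or variance moderation (0.059), and with the median of probe sets per gene neither Bcan (0.163) nor Sox10 (0.0741) passed. In the fry test the precursor list fell (adjusted p = 0.00209).

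Of 16 cholesterol biosynthesis genes 14 fell and none rose (15 adjusted over the list alone; adjusted p = 3.12e-07), and all 16 had a lower mean in EAE. Idi1 of isoprenoid synthesis (-1.85 ± 0.17), Cyp51, a sterol demethylase (-1.63 ± 0.19), and Insig1, a sterol-regulated inhibitor of the pathway (-1.35 ± 0.14), fell most. The list mean went from 7.99 ± 0.21 to 7.03 ± 0.12 (SD, n = 4), and its adjusted p was 0.120 with an estimated correlation. Relative to the myelin list it fell by 0.57 per array (exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give). Genes of cholesterol efflux and lipid uptake went the other way, 9 of 16 rising and none falling (9 rises and 1 fall adjusted over the list alone; adjusted p = 2.41e-05). They included Soat1, which esterifies cholesterol (2.34 ± 0.11), the exporter Abca1 (1.91 ± 0.20) and Olr1, a receptor for oxidised lipoprotein (1.76 ± 0.16). That list had an adjusted p of 0.0661 with an estimated correlation.

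**Figure D4:**
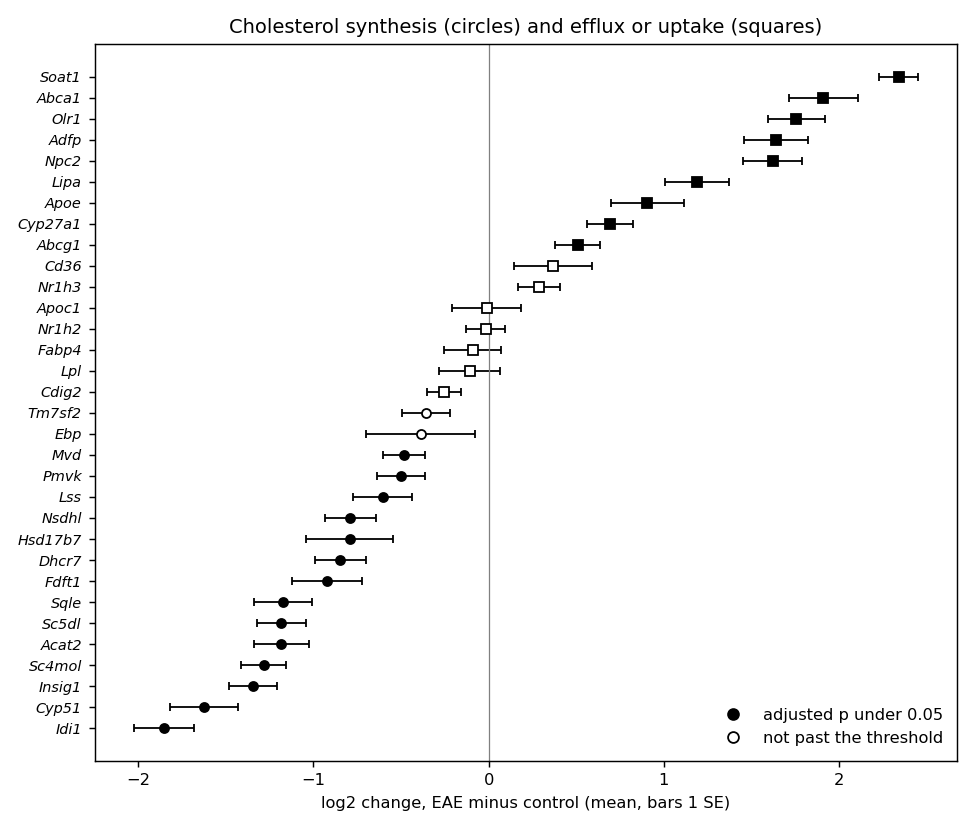
Log2 change, EAE minus control, of each measured gene of cholesterol biosynthesis (circles) and of cholesterol efflux and lipid uptake (squares), with bars of 1 SE from 4 rats per group; filled symbols have an adjusted p under 0.05. All 16 synthesis genes lie below 0, from -1.85 (Idi1) to -0.36 (Tm7sf2), and 9 efflux and uptake genes lie above 0 past the threshold.

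Neuronal genes fell moderately and widely. Of 30 voltage-gated ion channel genes 23 fell (23 adjusted over the list alone; adjusted p = 2.02e-08), with the sodium channel Scn1a (-1.06 ± 0.15), the potassium channel Kcnh7 (-1.04 ± 0.13) and the calcium channel subunit Cacna2d1 (-0.96 ± 0.11) lowest. Of 41 neurotransmitter receptors and transporters 24 fell (33 adjusted over the list alone; adjusted p = 2.61e-08), including the neuropeptide Npy (-0.94 ± 0.17), the kainate receptor Grik2 (-0.93 ± 0.11) and Gad2, which makes GABA (-0.89 ± 0.18). Of 26 genes of neuronal structure and synapses 15 fell (18 adjusted over the list alone; adjusted p = 0.000122), among them Nlgn1 (-0.96 ± 0.12), Cplx1 (-0.77 ± 0.12) and the neurofilament Nefh (-0.76 ± 0.14). No member of these 3 lists rose. With an estimated correlation the adjusted p was 0.190 for channels, 0.245 for receptors and transporters and 0.296 for structure and synapses. Relative to structural genes channels fell by 0.21 per array (exact permutation p = 0.0286).

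The remaining lists did not pass, though single members did. Of 11 endothelial and barrier genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p of the list = 0.956). Ly6c, read by 1 probe set, rose by 3.68 ± 0.34. The glucose transporter Slc2a1, chosen after its values were seen, rose by 0.59 ± 0.19. The organic anion transporter Slco1c1 (-0.76 ± 0.16) and the pericyte gene Rgs5 (-0.70 ± 0.16) fell. Of 9 genes of iron and heme handling 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.124), with Cp, a plasma ferroxidase (2.78 ± 0.12), Hmox1, which degrades heme (2.08 ± 0.26), Lcn2 and the iron exporter Slc40a1 (-0.72 ± 0.11) among them. The other fall was that of Hp, haptoglobin (-0.41 ± 0.11, chosen after its values were seen). In the endothelial and iron lists the median change was below 0 (-0.06 and -0.03) while the mean was above it (0.21 and 1.08), as was the direction of the test. The iron list passed as a rise with no filter on dim probe sets (adjusted p = 0.049) and in fry (8.33e-05). For neutrophil genes the median and mean were both -0.05 with a test direction above 0. Of 18 oxidative phosphorylation genes 4 fell (4 adjusted over the list alone; adjusted p = 0.248), Ndufs1 (-0.58 ± 0.13), Uqcrc2 (-0.47 ± 0.14), Uqcrfs1 (-0.44 ± 0.11) and Ndufv2 (-0.40 ± 0.11). The largest difference in that list was in cytochrome c, Cycs (-1.21 ± 0.43), which missed the threshold (adjusted p = 0.058). Ndufv2 and Cycs were chosen after their values were seen. Uqcrc2 had an adjusted p of 0.0503 to 0.0796 without control 193, control 194, control 196, EAE 217 or EAE 218, of 0.054 without variance moderation and of 0.138 with the median of probe sets. Of 21 splicing regulators 3 rose and 5 fell (3 and 5 adjusted over the list alone; adjusted p = 0.846). Khdrbs3 (-1.05 ± 0.12), Khdrbs2 (-0.77 ± 0.13) and Elavl3 (-0.77 ± 0.16), RNA-binding proteins of neurons, fell, and the splicing repressor Ptbp1 rose by 0.72 ± 0.11. The splicing list fell in fry (adjusted p = 0.0296).

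Markers of tissues next to the cord were measured beside these groups. Both measured adult haemoglobin genes fell, Hba-a2 by 2.43 ± 0.23 and Hbb by 2.26 ± 0.47, within a red blood cell list of 4 genes (2 fell, 2 adjusted over the list alone) that did not pass (adjusted p = 0.0859). It fell with the median of probe sets per gene (adjusted p = 0.0335) and in fry (0.00114). Of 9 Schwann cell genes Egr2 rose by 0.77 ± 0.17 and Cdh19 (-1.30 ± 0.18) and Sox10 fell (1 and 2 adjusted over the list alone; adjusted p = 0.661). Of 11 meningeal and fibroblast genes 1 rose (1 adjusted over the list alone; adjusted p = 0.257), the matrix protein Mgp (2.84 ± 0.57). None of 10 genes of muscle and fat passed (0 adjusted over the list alone; adjusted p = 0.248), the largest changes being -0.83 ± 0.36 for leptin, Lep, and -0.79 ± 0.42 for the myosin light chain Myl1. Lep passed without EAE 219 (adjusted p = 0.0404) and with no filter on dim probe sets (0.0455), and Myl1 with array quality weights (-1.53, adjusted p = 0.019). Control 194 was highest for Myl1, which differed by -0.30 without it, and Lep, at background in both groups, by -0.53 without EAE 241.

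The second comparison, the one for which exon arrays are made, asked where single exons departed from the rest of their gene. In Tnfrsf1a, a receptor for tumour necrosis factor, a probe set rose by 2.91 ± 0.31 more on the log2 scale than the gene's other probe sets, and in Icam1, an adhesion molecule, another rose by 2.84 ± 0.27 more. In Dlg1, a synaptic scaffold, a probe set fell by 2.13 ± 0.22 more than the others. In Ptprc, the leukocyte phosphatase CD45, whose exons are known to be skipped in turn in lymphocytes, a probe set rose by 1.86 ± 0.25 beyond the rise of the gene (4.09 ± 0.11). The controls of Tnfrsf1a, Icam1 and Ptprc and the EAE arrays of Dlg1 lay at the background of single probe sets there, the log2 value that 95% of olfactory receptor probe set values stayed under (5.33), so these relative changes are measured against it. These relative changes are means with SE from limma's diffSplice (n = 4 per group). The probe sets given were not alone in departing by 1 or more from the rest of their gene. In Tnfrsf1a 6 of 13 measured probe sets did so, in Icam1 4 of 8, in Ptprc 3 of 27 and in Dlg1 2 of 24.

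Of 5563 genes with at least 3 measured probe sets, 1482 (26.6%) passed the diffSplice F test at an adjusted p under 0.05. Among them 1130 had a gene-level change under 1, and in 654 of these at least 1 probe set differed from the rest by 1 or more. The share that passed went up with the size of the gene's own change, from 16.9% under 0.25 to 77.5% at 1 or more. The count was sensitive to the arrays and to the variance model: it was 861 without control 196, 915 without EAE 217 and 957 without EAE 241. It was 729 with a variance of its own for each probe set, a test chosen after seeing the data because 25.7% of diffSplice calls in the simulated data held no moved probe set (1.96% with its own variance).

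Of the 10 genes that the rule for named genes takes by smallest adjusted p 9 are described, and the 1 left out had a smaller adjusted p than these. Besides Tnfrsf1a, Icam1 and Dlg1 they were Ptpro, a receptor phosphatase (-1.51 ± 0.26), the hexokinase Hk3 (2.19 ± 0.28), the coagulation factor F8 (1.74 ± 0.30), Oplah (1.59 ± 0.27), the interleukin-21 receptor Il21r (2.80 ± 0.24) and Stxbp2, which acts in granule release (2.51 ± 0.31). The value given is the change of the probe set that departed most, relative to the rest of its gene. Probe sets departing by 1 or more numbered 5 of 22 in Ptpro, 5 of 15 in Hk3 and 5 of 30 in F8. They numbered 5 of 22 in Oplah, 2 of 8 in Il21r and 3 of 17 in Stxbp2. Adjusted p values of the 9 ran from 6.93e-18 (Ptpro) to 4.33e-13 (Stxbp2), and in all 9 the relative levels of the 4 EAE rats lay clear of the 4 controls. With a variance of its own for each probe set 8 of the 9 passed, F8 missing the threshold (adjusted p = 0.0544). The probe set of Ptpro lay at background in both groups, and those of Hk3, F8 and Stxbp2, like those of Tnfrsf1a and Icam1, in controls.

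**Figure D5:**
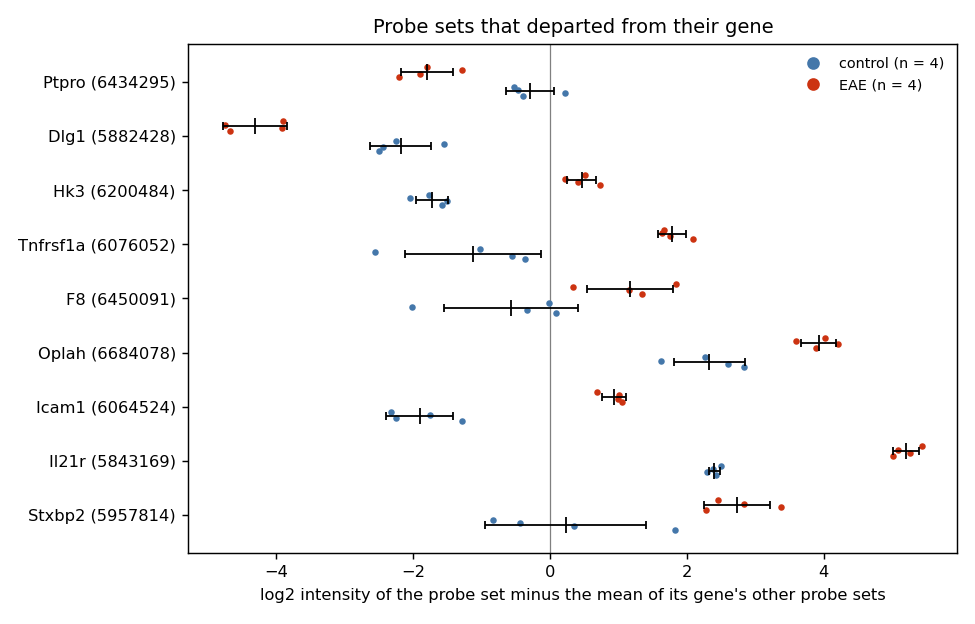
Log2 intensity of 1 probe set minus the mean of the other measured probe sets of its gene, for 9 of the 10 genes with the smallest adjusted p among those with a gene-level change under 1 and a probe set differing by 1 or more; points are arrays and bars the mean ± SD of 4 rats per group, with the probe set's number in parentheses. In Il21r the EAE rats lie above the controls by 2.80 on average, and in Dlg1 the relative level fell by 2.13.

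Of 42 tested genes with well known alternative exons 21 passed, and 22 adjusted over the list alone. With a variance of its own for each probe set 8 of the 21 passed: Ptprc, Cd44, Fn1, Mbp, Tpm3, Vcan, Slc8a1 and Fas. In fibronectin, Fn1, which rose by 2.41 ± 0.22, the relative level of a probe set fell by 2.28 ± 0.38 (its own log2 value was 5.94 ± 0.32 in controls and 6.11 ± 0.32 in EAE, SD). The death receptor Fas rose by 1.59 ± 0.11 with a probe set, at background, whose relative level fell by 1.36 ± 0.29. In Cd44 a probe set rose by 1.47 ± 0.36 more than the rest, though its relative levels overlapped between the groups. The sodium-calcium exchanger Slc8a1 (1.72 ± 0.29), tropomyosin Tpm3 (1.21 ± 0.24), the myelin basic protein gene Mbp (0.99 ± 0.21, at background) and versican, Vcan (0.81 ± 0.30), each had a probe set that changed upward relative to the rest. Probe sets departing by 1 or more numbered 11 of 54 in Fn1, 7 of 18 in Cd44 and 4 of 10 in Fas. They numbered 2 of 11 in Slc8a1, 1 of 6 in Tpm3 and 0 in Mbp and Vcan. Vcan lost its call without control 196, EAE 217, EAE 218 or EAE 219 (highest adjusted p = 0.0874). The other 13, Mag, Mapt, Nrxn2, Grin1, Camk2d, Bin1, App, Clta, Dnm2, Atp2b1, Atp2b4, Kcnma1 and Casp2, did not pass with a variance of its own for each probe set, and 10 of them also lost their call without at least 1 array, with adjusted p up to 0.472 for Atp2b1.

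Single probe sets were compared without regard to genes. Of 62176 measured probe sets 12661 changed in limma, 6343 upward and 6318 downward, and 4646 rose and 2271 fell by 1 or more. The largest rises were in probe sets of Cxcl13 (6685998; 3.07 ± 0.22 in controls and 11.60 ± 0.24 in EAE, SD) and Cxcl9 (6593607; 3.07 ± 0.50 and 11.51 ± 0.16). The largest falls were in probe sets with no gene name here, 6500747 (8.41 ± 0.68 and 4.56 ± 1.64) and 6317719 (7.56 ± 0.16 and 3.89 ± 1.04). The controls of the 2 rises and the EAE means of the 2 falls lay under the background of single probe sets, so these changes are measured against it.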

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

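The tests on control 195, on dilution by infiltrating cells and on other splits of the arrays for genes, probe sets and exon usage were chosen after the result was seen. For control 195 the tests of range and of early disease replaced 2 earlier ones, a slope that restated the SD of its array and the MHC class II list alone.

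In 13 of 334 groups of 4 arrays (3.89%), 1 array lay far from the other 3 by Dixon's test at its 95% critical value, given as the gap to the nearest array over the group's range. Chance alone gives about 1 in 20. Among list means, EAE 218 was high on chemokines (6.98 against at most 6.66; ratio 0.923) and EAE 219 low on proteases (7.29 against at least 7.42; ratio 0.867). Among control values, rat 196 was high for Lcn2 (ratio 0.870), Nlgn1 (0.852) and Cacna2d1 (0.879), and rat 193 was low for Il8rb (0.867) and Coro1a (0.882). EAE 218 was low for Ndufs1 (0.856). Among relative probe set levels, control 194 was high for Ptpro (0.832), EAE 241 low for Icam1 (0.854), EAE 219 high for Mag (0.900), and EAE 218 low for Bin1 (0.852) and Clta (0.838).

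Control 195 stood apart from the other controls on the second principal component. A compressed range of log2 values is unlikely as its only cause, since the root mean square deviation of its genes from the other controls went from 0.456 to 0.450 when all arrays were given the same distribution (highest other control 0.354). RNA of nerve root, meninges, blood or muscle stays open: it lay above all other controls on 0 of the 4 lists of other tissues, but its difference from the highest on Schwann genes was -0.04 (SD of the others 0.33), and it lay above 2 of the 3 others on Schwann, meningeal and muscle genes and below all 3 on red blood cell genes. Early disease stays open too: it lay at least 10% of the way to the EAE arrays on 8 of the 20 called lists, being 3 of the 15 that rose (T cell markers 26.4%) and 5 of the 5 that fell (myelin 75.9%), but 4.86% on MHC class II and -0.896% on interferon response. These distances use values as deposited, in which the genes of control 195 deviated from the other controls with a slope of -0.133 on their level. Bright lists are thereby lowered and dim ones raised on that array. The 5 fallen lists had control means of 6.85 to 8.71, and the 3 risen ones 4.46 to 5.04. Disease and the array's range therefore cannot be told apart on these 8 lists. No biological explanation was tested beyond other tissue and early disease.

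Neuronal, receptor and channel lists fell in EAE with the preset correlation, and none passed with an estimated correlation (adjusted p = 0.296, 0.245 and 0.190). If RNA of infiltrating cells diluted all cord cells alike, homeostatic astrocyte genes would fall as much, but the difference between the lists moved by -0.46 (97 and 14 genes; exact permutation p = 0.0286, the smallest possible). The test cannot decide on even dilution, because 3 of the 14 astrocyte genes rose past the threshold themselves (Slc1a3 by 1.15). The myelin list, not used in it, had a mean change of -0.39. That is close to structure and synapses (-0.38) and smaller than receptors (-0.56) and channels (-0.59). A shift of all genes of that brightness is unlikely, since 0% of 10000 random lists matched on level had a median as low as -0.53 (lowest -0.26). A lower level in neurons or fewer neurons may remain as hypotheses, which were not tested, and the astrocytes' own change in disease stays open.

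Changed exon usage was called in 77.5% of genes with a change of 1 or more. If dim probe sets that follow their gene less were the cause, a probe set's change would go up with its control level. In 177 such risen genes above background the median Spearman's rho over genes was -0.20 (51 above 0; sign test p = 3.35e-08). This cannot decide on dim probe sets, because the test followed the filter on them. A probe set under the filter's limit in all controls was kept only if it reached that limit on all EAE arrays. Some dim probe sets that did not follow their gene were thus removed beforehand, which favours a rho below 0. In 144 risen genes at background, rho was 0.60 with the level in other EAE arrays and -0.39 with that in other controls, so dim probe sets and changed exon usage cannot be told apart, because control values there hold little but background. Genes are not independent replicates.

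Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many changed genes in limma (2164, highest other 0), 1 as many probe sets (12661, highest other 0) and 1 as many genes with changed exon usage (1482, highest other 124). For these 3 counts the share is 2.86%, the smallest that 35 splits can give, which excludes chance at that level only. For gene lists 12 of 35 gave at least 20, with 24 the highest other, so this count of splits does not exclude chance for their number. The 11 others were among the 16 splits that swap 1 array of each group, which keep part of the difference between EAE and control, and the 18 that swap 2 reached at most 10.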

How the results depend on the processing

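The variance of its own for each probe set, the runs without control 195 and EAE 218, at the olfactory receptor background and centred on tested genes were chosen after the result was seen. Of the called genes that the rule names, 86 of 94 kept direction and call under each alternative run in which they were followed. So did 16 of the 31 genes it names for changed exon usage and 12 of 20 called lists. None of these was followed in the run that required a change of at least 1, nor any gene in a run that did not hold it. Genes with a smaller change lose their call by construction where a change of 1 is required. The rule picks large changes and small adjusted p, and the other called genes were not followed singly. With a change of at least 1 required, 526 genes, 6917 probe sets and 982 genes with changed exon usage passed, fewer by construction. With an estimated correlation 12 lists passed; with a variance of its own for each probe set 729 genes had changed exon usage. Without 1 array, counts ran from 1674 to 2340 genes, 8524 to 13451 probe sets, 861 (without control 196) to 2101 (without control 193) genes with changed exon usage, with 915 without EAE 217 and 957 without EAE 241, and 20 to 21 lists. Across scalings the median of all genes ran from -0.11 to -0.153, the latter after centring on the tested genes.

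Some values turned sign or direction, and the cause was not tested. Prf1 was 0.10 with no filter. The iron and heme list passed as a rise with fry (median -0.0343) and with no filter (median -0.0364), and its median was 0.0443 at the 50th percentile, 0.0443 at the olfactory receptor background, 0.0382 without both narrow arrays, and -0.0784 to 0.0336 without 1 array. That of splicing regulators was 0.0189 after quantile normalization and -0.0850 to 0.0167 without 1 array, that of endothelial genes 0.0584 with medians of probe sets and -0.11 to 0.0390 without 1 array, and that of neutrophil genes -0.14 to 0.0172 without 1 array. Signal over background limits the 902 genes at background in both groups. No paired analysis was possible because the groups share no replicate numbers.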

Other observations

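The added lists were written after Scd1, Ift80 and Lca5 had been seen, and their tests were fixed before those lists' values were seen. Ift80 (-1.13 ± 0.14), of intraflagellar transport, and Lca5 (-1.23 ± 0.14), of the cilium, fell in EAE and were chosen after their values were seen. Of 11 other genes of intraflagellar transport and the cilium 6 fell and none rose, including the motor Dync2h1 (-0.58 ± 0.10) and Tekt1 (-0.67 ± 0.13), with a median of -0.39. Dync2h1 and Tekt1 were chosen after their values were seen. The list passed with the preset correlation (adjusted p = 0.0146) and not with an estimated one (adjusted p = 0.157), so a fall of the whole group and falls of single members cannot be told apart, since the call rests on the correlation assumed.

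Scd1 fell among genes of fatty acid synthesis of which 2 rose and 6 fell out of 20 others (median -0.35). The 20 include Scd (-0.39 ± 0.19, adjusted p = 0.143), whose symbol is also the current one of Scd1, so the list is not free of that gene. Acsl3 (-0.97 ± 0.13) and Fads1 (-0.93 ± 0.21) fell and Acsl5 rose by 1.13 ± 0.15, all chosen after their values were seen. The list had an adjusted p of 0.25 (0.620 with an estimated correlation), and whether the group could have fallen as a whole remains open.

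Among splicing regulators Ptbp2 (-0.76 ± 0.10), a neuronal relative of Ptbp1, and Elavl2 (-0.72 ± 0.14) fell, and Cugbp2 (0.56 ± 0.12) and Sfrs10 (0.58 ± 0.16) rose, 4 genes chosen after their values were seen. Relative to efflux and uptake, cholesterol synthesis fell by 1.75 per array. Each list already parted all EAE rats from all controls, in opposite directions. The exact permutation p of this difference (0.0286) was therefore fixed in advance and adds nothing.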
